A study of Mus musculus with 6 samples.

How the data were processed

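Total RNA of 6 samples of mouse embryonic stem cells was extracted with TRIzol, labelled with biotin and hybridised to single-colour gene arrays at a core facility, per the labels. The deposited table holds 34760 features by 6 arrays, and its values, which lie between 2.29 and 14.50, were read as log2 intensity because they are never negative and span the range that log2 scanner intensities take. Neither the log base nor the background correction, summarization and normalization that the authors used is given in the sources used here. The median of all features was 7.13 and 7.16 in the control arrays, 7.16 and 7.16 in the arrays labelled GCSF, and 7.11 and 7.15 in the arrays labelled LIF/PD, so no column was centred on 0. The values were used as deposited, with no further normalization. For arrays there is no read depth, and the number of arrays, 2 in each of 3 groups, limits the precision.

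Genes were named through the platform's annotation table. Of the features, 21640 carried 1 gene symbol and 1321 carried several, from which no gene was named. All 6573 features whose identifiers lie below the first annotated one had no gene and were treated as a control block of the array and left out of the comparisons; a further 5226 features outside that block had no gene and were kept as unnamed. Among the 28187 features outside the control block, those with a mean log2 value at or above the 40th percentile, 6.70, were tested, which left 16912. For the gene lists, each of 12949 genes was represented by its feature with the highest mean.

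Differences were computed with limma 3.58.1 in R 4.3.3. One mean per group was fitted to all 6 arrays, the 3 contrasts were formed from these means, and variances were moderated with an intensity trend, which gave 3 residual and 8.4 total degrees of freedom. P-values were two-sided and adjusted with the Benjamini-Hochberg method over the 16912 features, and a feature was called at an adjusted p under 0.05. Errors are standard errors of the log2 difference from this fit (SE, n = 2 arrays per group) unless stated otherwise. The labels do not say that arrays of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

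The choices of test, filter, gene lists and named genes were made before the data were examined. The 22 gene lists, of 394 entries of which 322 were tested, comprised 4 main ones (STAT3 feedback and target genes, LIF-responsive pluripotency genes, ERK feedback genes and immediate early genes) and others for core pluripotency, interferon response, NF-kB inflammatory genes, SMAD targets, WNT targets, p53 targets, glycolysis and hypoxia, cholesterol synthesis, heat shock, the unfolded protein response, cell cycle, housekeeping, primitive endoderm, mesoderm and primitive streak, epiblast and neuroectoderm, trophoblast, feeder fibroblasts and cells resembling the 2-cell embryo. The 21 lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over 63 tests. Of these tests 17 passed, and with a correlation estimated from the data 0 passed. With an estimated correlation, camera takes its p-values from the 3 residual degrees of freedom. With a preset one it takes them from the number of genes. A call lost with an estimated correlation is therefore not by itself a sign of correlated members. Counts of list members are given over all features tested and also adjusted over the list alone.

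The genes named were, for each contrast, those with the 12 largest rises and 8 largest falls among called features with 1 symbol whose arrays did not overlap between the groups, called members of the 4 main lists, 23 genes named whatever their value, and of each other list up to 4 members with the smallest p. Where fewer than 10 features passed in a direction, the list was filled to 10 by the smallest p.

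The fit was tested on simulated data for the comparison of GCSF with control. Over 20 runs on 16912 features with 200 changed ones, 53.0% of features changed 1.2-fold were recovered, 99.1% at 1.5-fold and 99.9% at 2-fold, with 8.70% of calls false and on average 0.6 calls in an unchanged contrast. The share of false calls was above the threshold of 0.05, so in the simulation the adjusted p was too small. In the simulated list test for the same comparison, a shift of 0.2 in a list of 20 genes was called in 100% of runs and an unchanged list in 0.2%. The simulated features varied independently of each other, so these shares do not show how often lists of correlated genes are called. Because both comparisons against control used the same 2 control arrays, unchanged groups were simulated against shared controls 100 times.

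Alternatives covered the replicate number as a block, the arrays in the fit, the filter, quantile normalization and median centring, the variance model, a fold threshold, the handling of several features per gene, array weights, each array left out in turn, and other list tests. Of the list tests, limma's fry compares a list with no change, whereas camera, also on ranks, compares it with other genes. Features with a gene only, and the control block median as a covariate, were added after seeing the data.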

Results

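Transcript levels were measured on 6 arrays of mouse embryonic stem cells (ESCs) of strain C57Bl/6 that stably expressed the chimeric receptor GRgp-Y118F. In such receptors the ligand-binding part of the granulocyte colony-stimulating factor (GCSF) receptor is joined to the signalling part of gp130, the receptor subunit through which leukaemia inhibitory factor (LIF) activates the transcription factor STAT3. The Y118F change removes the tyrosine that couples gp130 to SHP2 and the ERK pathway. There were 2 untreated control arrays, 2 arrays labelled GCSF and 2 arrays labelled LIF/PD, that is LIF together with 1 uM PD0325901, an inhibitor of MEK, the kinase that activates ERK. Per the design text, cells were kept without serum for 6 h and treated for 1 h. Whether the untreated controls were also kept without serum is not given in the sources used here. If they were not, changes against control may include effects of serum withdrawal. The study asked which genes lie downstream of STAT3. Pearson correlations over the tested features were 0.997 to 0.998 between arrays of a group and 0.995 to 0.998 between arrays of different groups. Between any pair of arrays, 1 to 7 of the 16912 tested features had exactly equal values.

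Transcripts of ERK feedback genes check the label of the inhibitor. In the arrays labelled LIF/PD, the ERK phosphatase gene Dusp6 lay 0.03 ± 0.04 log2 from control and the ERK pathway inhibitor gene Spry4 0.05 ± 0.06, while in the arrays labelled GCSF Dusp6 fell by 1.56 ± 0.04 and Spry4 fell by 1.83 ± 0.06. This goes against the labels of these 2 groups. The groups were kept as labelled, and every direction given for GCSF or LIF/PD holds for the arrays that carry that label.

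The comparison of the arrays labelled GCSF with control addresses the genes that respond to the chimeric receptor. Socs3, the feedback inhibitor of JAK-STAT signalling, rose 8.78-fold (log2 change 3.13 ± 0.07, adjusted p = 2.70e-07), and its other feature differed by 0.51. Other genes that rose were Bcl3, a nuclear IkB protein, by 1.35 ± 0.05, the small GTPase gene Rhob by 1.28 ± 0.07, the noncoding RNA Rian by 1.31 ± 0.08, and the pluripotency factor gene Klf4 by 0.92 ± 0.06. Besides Spry4 and Dusp6, as above, the immediate early genes Egr1 and Myc fell, Egr1 by 1.49 ± 0.08 and Myc by 0.77 ± 0.04. In all, 136 features were higher and 62 lower, of which 41 and 15 changed at least 1.5-fold, and the features with 1 symbol named 112 and 48 genes.

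Of the 26 tested STAT3 feedback and target genes, 12 rose and 0 fell, and 14 did not pass. Adjusted over the list alone, 19 were higher and 1 lower. Besides Socs3 and Bcl3 the genes that rose included Stat3 itself (0.61 ± 0.05), the adhesion receptor gene Icam1 (0.96 ± 0.07), Gadd45g (0.84 ± 0.05), the kinase gene Pim3 (0.70 ± 0.05), Junb (0.59 ± 0.07), and the cytokine receptor genes Osmr (0.52 ± 0.06) and Lifr (0.35 ± 0.06). The list was higher than other genes (median log2 change 0.37, adjusted p = 1.60e-23 with camera, adjusted p = 0.0573 with an estimated correlation). Pim1 (-0.03 ± 0.06) and Il6st, which encodes gp130 (0.12 ± 0.04), did not pass, and Csf3r, the GCSF receptor gene, lay below the filter at 0.02 ± 0.10.

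Among 16 LIF-responsive pluripotency genes 5 rose and 2 fell, and adjusted over the list alone 9 were higher and 2 lower. The transcription factor genes Klf4, Klf5 (0.56 ± 0.04), Gbx2 (0.66 ± 0.08), Mycn (0.41 ± 0.04) and Sall4 (0.23 ± 0.03) rose, while Myc and Nr0b1 (-0.18 ± 0.03) fell. The list as a whole was higher (median 0.11, adjusted p = 0.000115, adjusted p = 0.133 with an estimated correlation). Tfcp2l1 (0.12 ± 0.04, adjusted p = 0.225) and Tbx3 (0.21 ± 0.05, adjusted p = 0.0959) did not pass. Of 23 core pluripotency genes, Tdgf1 (0.30 ± 0.03), Fgf4 (0.29 ± 0.03), Fbxo15 (0.35 ± 0.05) and Sall4 rose and Nr0b1 fell, 5 were higher and 3 lower adjusted over the list alone, and the list did not pass (adjusted p = 0.469). Pou5f1 (-0.04 ± 0.03), Sox2 (0.10 ± 0.04), Nanog (0.10 ± 0.03) and Esrrb (0.04 ± 0.03) did not pass.

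Of 21 ERK feedback genes 6 fell and 1 rose, and adjusted over the list alone 13 were lower and 2 higher. Besides Spry4 and Dusp6 those that fell were Epha2 (-0.64 ± 0.05), Dusp4 (-0.55 ± 0.06), Spry1 (-0.41 ± 0.07) and Fosl1 (-0.37 ± 0.07). Epha4 rose by 0.30 ± 0.05, and Spry2 did not pass at -0.26 ± 0.06. The list was lower than other genes (median -0.20, adjusted p = 4.05e-16, adjusted p = 0.0573 with an estimated correlation). Of 29 immediate early genes, which serum and growth factors induce within minutes, 9 rose and 3 fell, or 10 and 6 adjusted over the list alone. Jun (0.73 ± 0.07), Atf3 (0.71 ± 0.07), Btg2 (0.69 ± 0.05), Ccn1 (0.66 ± 0.06), Dusp1 (0.58 ± 0.03), Fosl2 (0.54 ± 0.07) and Klf6 (0.48 ± 0.05) rose together with Junb and Zfp36 (0.39 ± 0.06). Egr1, Myc and Fosl1 fell and Fos did not pass (-0.29 ± 0.09). The list was higher (adjusted p = 0.0213, adjusted p = 0.459 with an estimated correlation). It did not pass without control replicate 2 (0.259), without GCSF replicate 2 (0.235), without an intensity trend in the variances (0.0685), with fry (0.0691) or on ranks (0.343).

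**Figure D1:**
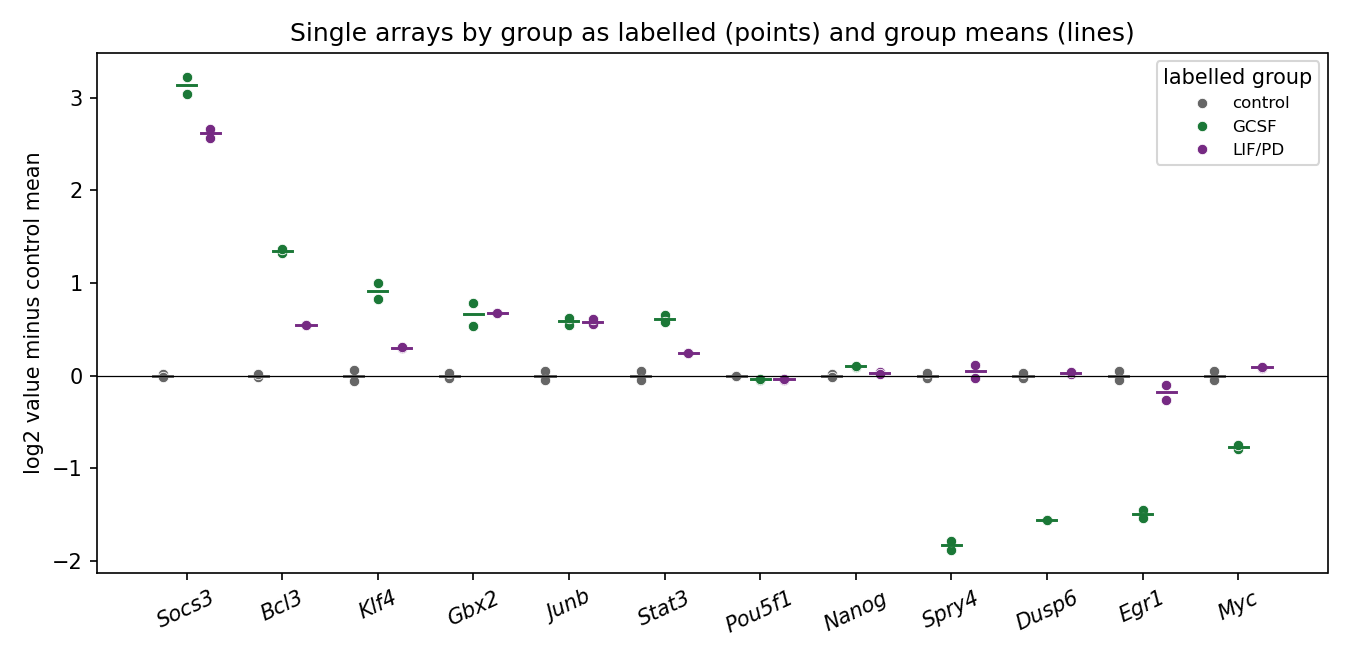
Log2 values of 12 genes on the single arrays (points) and their group means (lines), as differences from the control mean, with groups as labelled (grey control, green GCSF, purple LIF/PD). Socs3 rose in both, by 3.13 under GCSF and 2.62 under LIF/PD, while Spry4, Dusp6, Egr1 and Myc lay below control on both arrays labelled GCSF.

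Interferon response genes rose in 5 of 18 cases with 0 falls (5 and 0 adjusted over the list alone), namely Ifit1 (0.64 ± 0.12), Irf9 (0.52 ± 0.05), Irf1 (0.43 ± 0.05, with 0.12 on its other feature), Stat2 (0.40 ± 0.06) and Usp18 (0.35 ± 0.06). As a list they were higher (adjusted p = 8.02e-07, adjusted p = 0.108 with an estimated correlation). Irf1 and Irf9 also stand in the STAT3 list. Of 12 SMAD target genes 3 fell, Id3 (-0.81 ± 0.07), Smad7 (-0.33 ± 0.04) and Tgif1 (-0.28 ± 0.03), and adjusted over the list alone 4 were lower and 1 higher. That list was lower (adjusted p = 0.000171, adjusted p = 0.213 with an estimated correlation). The glycolysis and hypoxia list, in which Hk2 (0.47 ± 0.05) alone of 15 rose over all features and 2 did adjusted over the list alone, was higher (adjusted p = 0.0111, adjusted p = 0.246 with an estimated correlation), but not without GCSF replicate 2 (0.171). The p53 target list, in which Btg2 and Plk2 (0.47 ± 0.05) rose out of 12 and 3 were higher and 1 lower adjusted over the list alone, was higher as well (adjusted p = 0.0350, adjusted p = 0.346 with an estimated correlation), a call that ended whichever array was left out. The adjusted p was 0.0571 and 0.0505 without control replicates 1 and 2, 0.0659 and 0.0602 without GCSF replicates 1 and 2, and 0.0610 and 0.0527 without LIF/PD replicates 1 and 2.

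Markers of other cell types did not pass as lists. Single members rose: the trophoblast gene Tfap2c (0.74 ± 0.06), the neural gene Pax6 (0.54 ± 0.07), Lama1 of the endoderm list (0.43 ± 0.05) and Col3a1 of the fibroblast list (0.29 ± 0.05). The adjusted p values of the lists were 0.186 for trophoblast (1 higher and 4 lower adjusted over the list alone), 0.761 for epiblast and neuroectoderm (1 and 0), 0.700 for primitive endoderm (1 and 0), 0.546 for feeder fibroblasts (1 and 1) and 0.209 for mesoderm and primitive streak (0 and 2). Ccl2 fell (-0.45 ± 0.05) and Icam1 rose in the NF-kB list (adjusted p = 0.805, 1 and 2 adjusted over the list alone). Hmgcs1 (0.21 ± 0.03) rose in the cholesterol list (adjusted p = 0.373, 2 and 0) and Tfrc (0.24 ± 0.03) in the housekeeping list (adjusted p = 0.932, 1 and 0). No member passed over all features with limma in the mesoderm list (2 of 7 at an unadjusted p under 0.05) or in 4 further lists, namely heat shock (adjusted p = 0.207, 1 and 0 adjusted over the list alone, 2 of 10 members at an unadjusted p under 0.05), unfolded protein response (0.158, 1 and 0, 3 of 16), WNT targets (0.779, 1 and 0, 2 of 10) and cell cycle (0.997, 0 and 0, 3 of 16). None of the 11 genes of the list for cells resembling the 2-cell embryo was tested.

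The largest changes outside the lists included rises of Dapp1 (0.88 ± 0.06), D730005E14Rik (0.82 ± 0.07, with 0.22 on its other feature), Elobl (0.81 ± 0.08) and Fgf10 (0.78 ± 0.08) and a fall of the noncoding RNA Platr8 (-0.76 ± 0.12). Features of 2 genes that fell did not speak for the whole gene: Rbpj fell by 1.28 ± 0.06 on 1 feature and differed by -0.05 on the other, and Rpl38 fell by 0.96 ± 0.17 on 1 feature while its other 3 differed by -0.07 to -0.16. That feature of Rpl38 also differed from control by -1.02 in the arrays labelled LIF/PD, where it was not called, so its fall was not particular to GCSF. Of 60 called named genes 37 passed with any array left out. Socs3, Bcl3, Rhob, Rian, Klf4, Stat3, Spry4, Dusp6, Egr1 and Myc were among these. The 23 others were Gbx2, Lifr, Sall4, Nr0b1, Fgf4, Fbxo15, Epha4, Spry1, Fosl1, Fosl2, Zfp36, Irf1, Stat2, Usp18, Smad7, Tgif1, Pax6, Lama1, Col3a1, Hmgcs1, Tfrc, Platr8 and Rpl38. Of them 21 were lost without control replicate 1 and 15 without control replicate 2. At an unadjusted p under 0.05 there were 2049 features, against 846 by chance. The 198 calls dropped to 88 without control replicate 1, 108 without control replicate 2 and 118 without GCSF replicate 1, to 125 without an intensity trend in the variances, and to 99 with the control block median of each array as a covariate. That median was 6.84 in GCSF replicate 1, against 6.66 and 6.71 in the controls. Because a left-out array or the covariate also costs power, these drops do not by themselves show that the calls rest on particular arrays.

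By its label, the comparison of the arrays labelled LIF/PD with control asks which genes respond to LIF when MEK is inhibited. Dusp6 and Spry4, given above, showed no sign of that inhibition. Socs3 rose 6.15-fold (2.62 ± 0.07, adjusted p = 1.21e-06). The other 9 features that rose were those of Gbx2 (0.68 ± 0.08), Junb (0.58 ± 0.07), Bcl3 (0.55 ± 0.05), the WNT pathway gene Dact1 (0.52 ± 0.05), Pim3 (0.51 ± 0.05), Klf5 (0.43 ± 0.04), Gadd45g (0.43 ± 0.05), Dusp1 (0.40 ± 0.03) and the lysophosphatidic acid receptor gene Lpar6 (0.37 ± 0.04). The 1 feature that fell belonged to the splicing factor gene U2af1 (-0.61 ± 0.07), whose other feature differed by 0.05. Adjusted p for these 10 further calls lay between 0.00791 and 0.0400.

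STAT3 feedback and target genes rose in 5 of 26 cases with 0 falls, and 12 were higher and 0 lower adjusted over the list alone. As a list they were higher (median 0.13, adjusted p = 5.39e-18, adjusted p = 0.0573 with an estimated correlation). Stat3 (0.24 ± 0.05, adjusted p = 0.258), Icam1 (0.51 ± 0.07, adjusted p = 0.0923) and Osmr (0.25 ± 0.06, adjusted p = 0.443) did not pass. Of 16 LIF-responsive pluripotency genes Gbx2 and Klf5 rose, and 5 were higher and 0 lower adjusted over the list alone. Together they were higher than other genes (median 0.04, adjusted p = 3.07e-06 with camera, adjusted p = 0.108 with an estimated correlation). The mean of 0.14 lay well above that median, and 14 genes did not pass, so a few genes carried much of the difference. Of the 18 genes fixed for this list, 9 also stand in another list. Klf4 (0.30 ± 0.06, adjusted p = 0.374), Myc (0.09 ± 0.04), Tfcp2l1 (0.00 ± 0.04) and Tbx3 (0.23 ± 0.05) did not pass. Core pluripotency genes as a list were higher (median 0.03 over 23 genes, adjusted p = 0.0393, adjusted p = 0.454 with an estimated correlation) although no member passed, over all features or adjusted over the list alone, and 7 had an unadjusted p under 0.05 with limma. The values were -0.04 ± 0.03 for Pou5f1, 0.11 ± 0.04 for Sox2, 0.03 ± 0.03 for Nanog and 0.01 ± 0.03 for Esrrb. This call ended without control replicate 2 (0.634), either GCSF replicate (0.0514 and 0.0668) or either LIF/PD replicate (0.113 and 0.0881). Cholesterol synthesis genes were also higher as a list (adjusted p = 0.0205, adjusted p = 0.454 with an estimated correlation), with no member past the threshold and 1 of 14 at an unadjusted p under 0.05, but not without control replicate 2 (0.105) or LIF/PD replicate 1 (0.130).

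No ERK feedback gene of 21 passed in the arrays labelled LIF/PD, 2 had an unadjusted p under 0.05, and 1 was higher and 0 lower adjusted over the list alone. The list gave an adjusted p of 0.994, with a median of 0.02 while the test pointed down. Egr1 (-0.18 ± 0.08), Dusp4 (0.04 ± 0.06), Epha2 (-0.05 ± 0.05), Spry1 (-0.08 ± 0.07), Spry2 (0.32 ± 0.06) and Fosl1 (-0.01 ± 0.07) did not pass. The 95% interval of the Dusp6 change ran from -0.06 to 0.12. Of 29 immediate early genes Junb and Dusp1 rose, 3 were higher adjusted over the list alone, and the list did not pass (adjusted p = 0.0663), except without control replicate 1 (0.00209) and under 3 other settings (0.0191 to 0.0493). Jun (0.11 ± 0.07), Btg2 (0.01 ± 0.05) and Fos (-0.03 ± 0.09) were among those that did not pass. The remaining 15 lists with enough members did not pass, with adjusted p from 0.171 for interferon response, mesoderm, neuroectoderm and the unfolded protein response to 0.932 for SMAD targets, WNT targets and cell cycle. Interferon response passed without control replicate 1 (0.0189). No member of these lists passed over all features with limma, and at most 3 in any of them had an unadjusted p under 0.05. Adjusted over the list alone 2 interferon response genes were higher, 1 each of the NF-kB, neuroectoderm, trophoblast, unfolded protein response and glycolysis lists, and 0 of the others.

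At an unadjusted p under 0.05 there were 1114 features, against 846 by chance. Of the 11 calls 7 remained without either GCSF replicate, and only that of Socs3 remained without either control replicate or without either LIF/PD replicate, and with variances fitted without an intensity trend. Conversely, 24 or 27 genes were called when the features of a gene were averaged or reduced to the one with the highest mean.

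**Figure D2:**
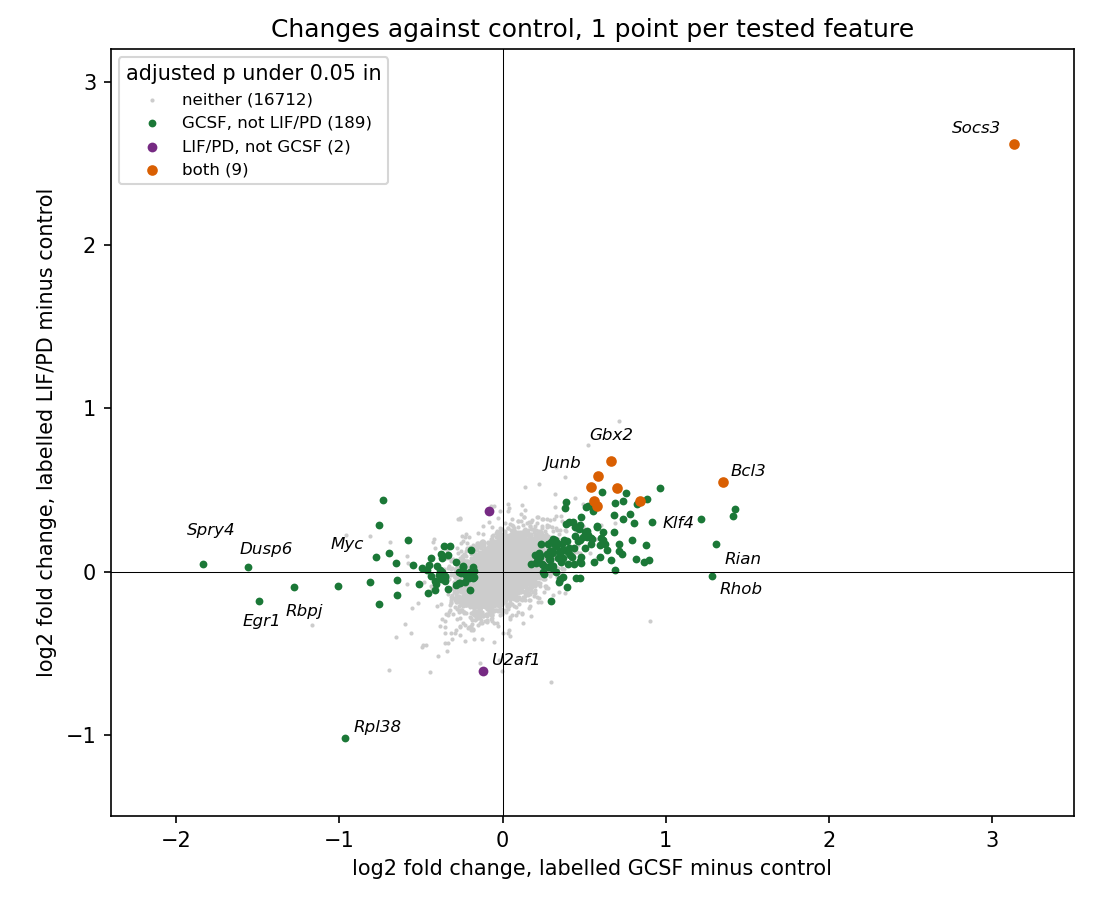
Log2 fold changes against control of the arrays labelled GCSF (horizontal) and LIF/PD (vertical), 1 point per tested feature, coloured by whether the adjusted p was under 0.05 in either comparison. The 9 features past it in both lie in the upper right, and Spry4, Dusp6 and Egr1 lie far left, near 0 on the vertical axis.

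The genes changed the same way under both labels address what GCSF and LIF share. They were Socs3, Gbx2, Junb, Bcl3, Dact1, Pim3, Klf5, Gadd45g and Dusp1, all higher in both, and no feature was lower in both by limma (75 were lower in both at an unadjusted p under 0.05, 297 higher). The rises under the 2 labels were 0.66 and 0.68 for Gbx2, 0.59 and 0.58 for Junb, 3.13 and 2.62 for Socs3, and 1.35 and 0.55 for Bcl3, given for GCSF first. Independent lists of these sizes would share 0.0804 higher features, and unchanged groups simulated against the same 2 controls shared 0.170 on average and at most 2. In that simulation no feature changed in either group, so few were called and few could be shared. It is therefore no baseline for sharing when 1 group has many changed features. Of the 136 features higher under GCSF 125 were positive under LIF/PD, and of the 62 lower ones 36 were negative. The same-sign share over both directions was 81.3%. In the simulated unchanged groups it was 91.0%, taken over as many features with the smallest p. There the shared controls alone make the signs alike, so 91.0% is no baseline for features that changed under GCSF. The correlation of log2 fold changes across features, which are not independent replicates, was 0.477, against 0.499 ± 0.00855 (SD) in the simulation, and the covariance was 0.00497 against 0.00242, a difference of 0.00255. The simulated correlation comes from the shared controls alone, so the observed one does not show a shared response. The 2 control arrays could not be split into parts of 2 arrays each, so part of the excess over independent lists may come from the shared controls. It is also not given whether the controls were kept without serum. An effect of serum withdrawal on these 9 features therefore cannot be told apart from a response that GCSF and LIF share. The 9 features became 1 without either control replicate or either LIF/PD replicate, or without an intensity trend, and 22 or 24 when the features of a gene were averaged or reduced to the one with the highest mean.

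The direct comparison of the arrays labelled LIF/PD with those labelled GCSF shows where the 2 treatments differ. ERK feedback genes were higher under the LIF/PD label: Spry4 by 1.88 ± 0.06 (adjusted p = 5.21e-06), Dusp6 by 1.59 ± 0.04 (adjusted p = 9.69e-07), Dusp4 by 0.59 ± 0.06, Epha2 by 0.59 ± 0.05 and Spry2 by 0.58 ± 0.06. Egr1 (1.31 ± 0.08), Platr8 (1.04 ± 0.12), Myc (0.86 ± 0.04) and the chemokine genes Ccl7 (0.81 ± 0.04) and Ccl3 (0.77 ± 0.08) were also higher. Lower under the LIF/PD label were Rhob (-1.31 ± 0.07), Rian (-1.14 ± 0.08), Bcl3 (-0.80 ± 0.05), Jun (-0.63 ± 0.07), Klf4 (-0.62 ± 0.06) and Socs3 (-0.51 ± 0.07). In all 68 features were higher and 75 lower, 17 and 15 of them by at least 1.5-fold.

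Of 21 ERK feedback genes these 5 were higher and 0 lower, or 12 and 1 adjusted over the list alone. As a list they were higher (median 0.21, adjusted p = 6.21e-15, adjusted p = 0.0573 with an estimated correlation). Of 26 STAT3 genes 5 were lower and 0 higher, or 12 and 0 adjusted over the list alone: Bcl3, Socs3, Icam1 (-0.45 ± 0.07), Gadd45g (-0.41 ± 0.05) and Stat3 (-0.37 ± 0.05). That list was lower (median -0.13, adjusted p = 4.60e-11, adjusted p = 0.0573 with an estimated correlation). Gbx2 (0.01 ± 0.08), Junb (0.00 ± 0.07), Zfp36 (0.04 ± 0.06) and Pim3 (-0.18 ± 0.05) did not pass. Interferon response genes Stat2 (-0.35 ± 0.06) and Usp18 (-0.41 ± 0.06) were lower, and of 18 genes 4 were lower and 0 higher adjusted over the list alone. This list was lower (adjusted p = 1.59e-05, adjusted p = 0.130 with an estimated correlation). SMAD targets Id3 (0.75 ± 0.07), Smad7 (0.43 ± 0.04) and Tgif1 (0.20 ± 0.03) were higher, and 6 were higher and 1 lower of 12 adjusted over the list alone. This list was higher (adjusted p = 0.000171, adjusted p = 0.213 with an estimated correlation). Glycolysis and hypoxia genes were lower as a list (adjusted p = 0.0422, adjusted p = 0.346 with an estimated correlation) with no member past the threshold and 4 of 15 at an unadjusted p under 0.05, but not without GCSF replicate 2 (0.392) or LIF/PD replicate 1 (0.179).

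Of the LIF-responsive pluripotency genes Klf4 was lower and Myc and Nr0b1 (0.21 ± 0.03) higher, and 2 were higher and 5 lower of 16 adjusted over the list alone. The list did not pass (adjusted p = 0.128), except without GCSF replicate 1 (0.0483). Of the immediate early genes Egr1 and Myc were higher and Jun, Btg2 (-0.68 ± 0.05), Ccn1 (-0.60 ± 0.06), Atf3 (-0.55 ± 0.07) and Klf6 (-0.39 ± 0.05) lower, or 4 and 7 of 29 adjusted over the list alone. This list did not pass (adjusted p = 0.133), except without GCSF replicate 1 (0.0128), with a filter at the 60th percentile (1.13e-05) or with the control block covariate (0.00163). Of core pluripotency genes Utf1 (0.23 ± 0.03) and Nr0b1 were higher and Tdgf1 (-0.17 ± 0.03) lower, while Pou5f1 (0.00 ± 0.03), Sox2 (0.01 ± 0.04) and Nanog (-0.07 ± 0.03) did not pass, nor did the list (adjusted p = 0.912, 3 higher and 4 lower adjusted over the list alone). The other 13 lists did not pass either, with adjusted p from 0.124 for p53 targets to 0.932 for mesoderm, cell cycle and housekeeping. Their called members were Ccl2 (0.49 ± 0.05), higher, and Icam1, lower, in the NF-kB list (3 higher and 2 lower adjusted over the list alone), Lama1 (-0.34 ± 0.05) in the endoderm list (0 and 1) and Btg2 in the p53 list (1 and 3). In the lists with no called member, those adjusted over the list alone were 2 higher and 1 lower for trophoblast, 2 higher for neuroectoderm, 1 higher for mesoderm, 2 lower for heat shock, and 1 lower each for fibroblasts, cholesterol synthesis and housekeeping. The unfolded protein response, WNT and cell cycle lists had 0, and at most 5 members of any of these 10 lists had an unadjusted p under 0.05. Lower genes outside the main lists included the chaperone gene Dnajb4 (-0.58 ± 0.08). Among other genes that were higher were Mir674 (0.70 ± 0.06), Trim36 (0.61 ± 0.09), and Rbpj and Top2a on 1 feature each (1.18 ± 0.06 and 0.62 ± 0.10), whose other features differed by 0.05 and -0.05. Of 38 called named genes 16 passed with any array left out. Those that did not include Socs3, Stat3, Klf4, Icam1, Gadd45g, Jun, Atf3, Dusp4 and Spry2, all lost without LIF/PD replicate 1. At an unadjusted p under 0.05 there were 1994 features, against 846 by chance. The 143 calls became 82 and 80 without control replicates 1 and 2, 60 and 91 without GCSF replicates 1 and 2, 30 and 47 without LIF/PD replicates 1 and 2, and 82 with the 4 arrays of these groups alone. The split of 68 higher and 75 lower became 42 and 18 without GCSF replicate 1, and 17 and 9 with the control block covariate.

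**Figure D3:**
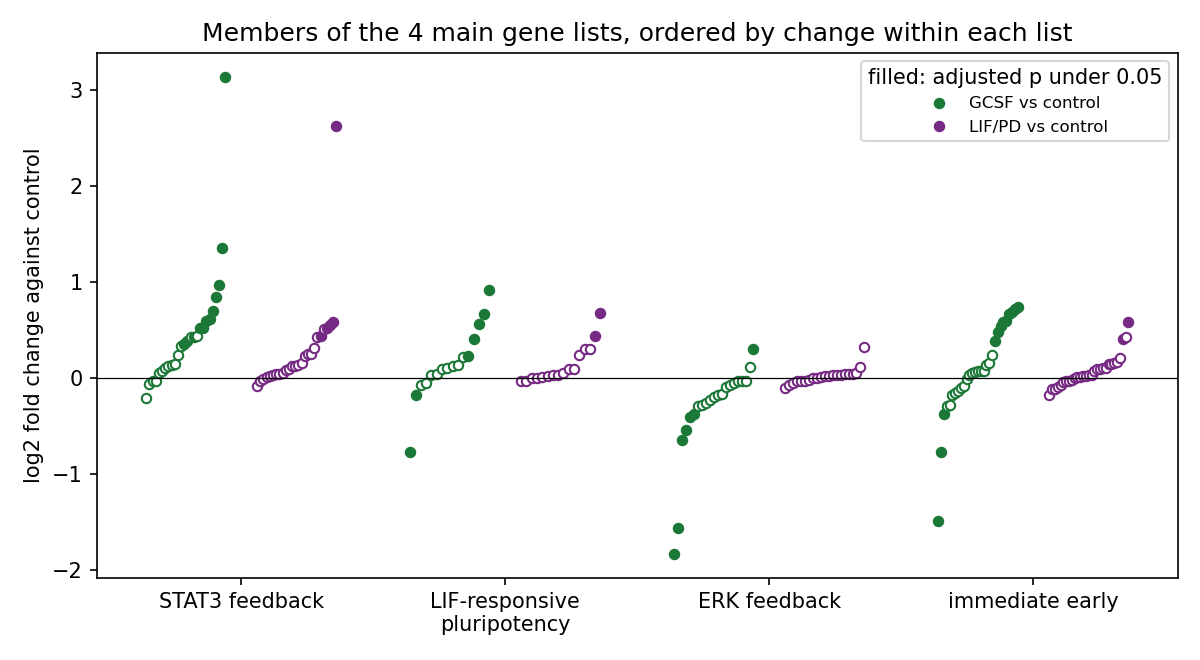
Log2 fold changes against control of the tested members of the 4 main gene lists, ordered by size within each list, for the arrays labelled GCSF (green) and LIF/PD (purple); filled points had an adjusted p under 0.05. ERK feedback genes had 6 members lower and 1 higher under GCSF and 0 called under LIF/PD.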

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

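The tests of features outside the comparisons, given here, were chosen after the results had been seen. The median log2 value of the control block, the features with no gene that were left out of the comparisons, was 6.84 in GCSF replicate 1, above both controls (6.66 and 6.71) and GCSF replicate 2 (6.71), while the arrays labelled LIF/PD lay at 6.58 and 6.68.

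Tested on its own with limma, the control block gave 0 features higher and 11 lower in the arrays labelled GCSF than in control (534 at an unadjusted p under 0.05 of 6573). The changes of these 11 ran from -0.603 to -1.014, from values between 8.36 and 11.30 in the control arrays. The block thus holds features with signal well above its median that differed between the groups, so its median is only a rough measure of background. In the arrays labelled LIF/PD 1 was higher and 0 lower, with 374 at an unadjusted p under 0.05. That feature, 10340239 (adjusted p = 0.0273), stood at 5.79 and 5.71 on the arrays labelled LIF/PD and at 4.44 and 2.41 on those labelled GCSF. Its values of 2.37 and 2.49 in control lay at or near the lowest of those arrays (2.37 and 2.29), so no fold is given. It has no gene name in the annotation used here.

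Of the 11275 features below the filter, tested on their own, 2 were higher and 1 lower in the arrays labelled GCSF than in control, with 622 at an unadjusted p under 0.05. Named after their values were seen, the higher ones were the homeobox gene Hesx1 (1.11 ± 0.09, adjusted p = 0.0150) and the muscle gene Trdn (1.05 ± 0.10, adjusted p = 0.0293), and the lower one was Tax1bp3 (-2.02 ± 0.22, adjusted p = 0.0359). Their means lay below the filter value of 6.70, which is within the range of the control block medians (6.58 to 6.84). Their signal is therefore not shown to exceed background, and the sizes of these changes are uncertain. In the arrays labelled LIF/PD 0 features passed, with 621 at an unadjusted p under 0.05.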

How the results depend on the processing

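The alternatives of features with a gene only and the control block median as a covariate were chosen after seeing the data. No result changed sign past the threshold. Of 109 calls of named genes 39 passed under every alternative run; over all alternatives the named genes gave 6462 values on the same side of the threshold, 402 that lost and 98 that gained a call, and the other lists 1012, 48 and 5. The arrays carry no measure of signal over background, so dim features could be judged only by the filter; with no filter 168, 12 and 124 features were called.

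Counts for GCSF against control, LIF/PD against control, LIF/PD against GCSF and the features shared by the first 2 were 198, 11, 143 and 9. They became 125, 1, 71 and 1 without an intensity trend, and 56, 3, 32 and 2 with a threshold of 1.5-fold, which by construction keeps fewer. With the mean of a gene's features LIF/PD gave 24 and the shared set 22, and with its highest-mean feature 27 and 24. With the 4 arrays compared alone, LIF/PD against GCSF gave 82. The covariate gave 99, 26 and 5 for GCSF, LIF/PD against GCSF and the shared set (LIF/PD against control gave 6 higher and 2 lower). Leaving out 1 array, the lone array being assumed to vary like the other groups, gave 88 to 164, 1 to 7, 30 to 91 and 1 to 6. The correlation of 0.477 became 0.456 with a filter at the 60th percentile, 0.452 with the mean of a gene's features, 0.292 with the covariate and 0.401 to 0.624 with 1 array left out. The cause was not tested where none is given.

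With an estimated correlation the list tests gave an adjusted p of 0.0573 for the STAT3 list in all 3 comparisons and for the ERK list in the 2 that passed. It was 0.133 and 0.108 for the LIF-responsive list and 0.459 for immediate early genes under GCSF. The estimated correlation was -0.0123 for the STAT3 list and 0.0172 for the ERK list, near the preset 0.01. For these lists the losses therefore do not show strongly correlated members. They follow from the 3 residual degrees of freedom that camera uses with an estimated correlation, in place of the number of genes. In the same comparisons the STAT3 list passed on ranks (4.31e-06 to 0.000403) and with fry (0.00192 to 0.00745). The ERK list did so too (1.21e-05 and 4.11e-05 on ranks, 0.00192 in both with fry). The immediate early list under GCSF also gave 0.0685 without an intensity trend and 0.343 on ranks, and 0.0691 with fry, which compares it with no change. Under LIF/PD against control it passed with no filter (0.0191), the 60th percentile filter (0.0235) and quantile normalization (0.0493), and against GCSF with the 60th percentile filter (1.13e-05) and the covariate (0.00163). With 1 array left out it ran from 0.000737 to 0.259, 0.00209 to 0.586 and 0.0128 to 0.669 in the 3 comparisons, and the LIF-responsive list in LIF/PD against GCSF from 0.0483 to 0.380. Quantile normalization and median centring gave 164 and 173 calls for GCSF.

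Arrays with the same replicate number did not deviate together: the correlations of their deviations from the group means were 0.0071, 0.084 and 0.099. With the replicate block the counts were 195, 9, 165 and 7. The 2 alternatives on an offset were not run because the table is on a log scale, and robust moderation and the fold threshold were not run for the list tests.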

Other observations

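The tests of Rian, of the ERK feedback genes and of the shares of each rise in this part were chosen after the results had been seen. In the arrays labelled GCSF the chemokine gene Ccl7 fell by 0.69 ± 0.04, Ccl3 fell by 0.58 ± 0.08 and Ccl2 fell by 0.45 ± 0.05. Under LIF/PD they lay at 0.11, 0.19 and 0.04, none of which passed. They were set side by side after their values were seen, no list of chemokines was tested, and other chemokine genes such as Ccl5 (-0.05) and Cxcl1 (-0.01) did not pass under GCSF. The BMP ligand gene Bmp4 fell by 0.44 ± 0.04 under GCSF and lay at 0.09 under LIF/PD. Lpar6 was called under LIF/PD at 0.37 and lay at -0.08 ± 0.04 under GCSF, and the direct difference of 0.45 passed (adjusted p = 0.00197). Etv5, an ERK-responsive transcription factor gene, differed by -0.03 on its feature with the higher mean and by -0.25 ± 0.04 (adjusted p = 0.0306) on the other. Bmp4 and the second feature of Etv5 were singled out after their values were seen.

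Of 21 ERK feedback genes 6 were lower, 1 was higher and 14 did not pass in the arrays labelled GCSF (list adjusted p = 4.05e-16, adjusted p = 0.0573 with an estimated correlation), while 0 passed in those labelled LIF/PD with limma (2 at an unadjusted p under 0.05), although that label names the MEK inhibitor. A single outlying GCSF array as the whole cause is argued against by the test over all 21 members, which were lower without GCSF replicate 1 (median -0.20, adjusted p = 1.18e-15) and without GCSF replicate 2 (median -0.21, adjusted p = 6.21e-12), both with the preset correlation. Exchanged labels of the GCSF and LIF/PD arrays may account for the pattern, as may signalling through the chimeric receptor that lowered ERK output together with an inhibitor that did not act. The list medians, 0.21 for LIF/PD minus GCSF and 0.0188 for LIF/PD minus control, follow from the pattern itself and decide for neither. These 2 explanations cannot be told apart, because no group had LIF or the inhibitor alone.

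Rian, a noncoding RNA of the imprinted Dlk1-Dio3 region, was higher under GCSF by 1.31 ± 0.08 and lay at 0.17 under LIF/PD. With each array's control block median as a covariate the change was 1.28 ± 0.11 (adjusted p = 0.00334 with limma). That median was raised in GCSF replicate 1 alone (6.84, against 6.71 in GCSF replicate 2), while Rian stood at 8.16 and 8.23 on these arrays. The covariate could thus take away little of the change, and the test does not decide whether background signal contributed. If a different imprinting state of the culture acted alike on Meg3, which is transcribed from the same domain, Meg3 would have risen by a large part of the rise of Rian. Meg3 lay at 0.23 ± 0.08 (adjusted p = 0.296 with limma). How such a state acts on these transcripts was not measured. In control Rian stood at 6.91 and 6.87, near the control block medians, and Meg3 at 9.67 and 9.79, so their log2 changes may not compare and the test does not decide. Of 22 tested features that name genes of the region, with a median of 0.09, 4 were called higher and 0 lower under GCSF, of which 1 names Rian, 1 names both Rian and AF357355 and so no single gene, and the others were Mir341 (0.44 ± 0.06) and Mir329 (0.48 ± 0.09), singled out after their values were seen; with the covariate their changes were 0.40 ± 0.08 and 0.54 ± 0.11, with larger errors (adjusted p = 0.133 for both). A response of Rian to the treatment is a hypothesis that stays open and was not tested.

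Of the 17 STAT3 and LIF target genes that rose under GCSF, and were selected for that rise, 6 were lower in the arrays labelled LIF/PD than in those labelled GCSF. The STAT3 list was lower (adjusted p = 4.60e-11, adjusted p = 0.0573 with an estimated correlation) and the LIF-responsive list did not pass (adjusted p = 0.128). A smaller share of responding cells could give this only if every gene kept about 1 common share of its linear rise. The best common share was 50.4%, but Klf4 kept 26.2%, Bcl3 30.0%, Stat3 34.9% and Socs3 66.2%, while Junb kept 99.0%, Gbx2 103% and Zfp36 112% (approximate chi-square test of equal shares, p = 3.51e-30), which argues against a smaller share of responding cells as the whole cause. Which treatment gave the smaller rises depends on the labels of these 2 groups, which are in doubt, and no biological explanation was tested.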
